A study of Mus musculus with 186 samples.

How the data were processed

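RNA of single inner cells was sequenced from CD-1 mouse embryos, per the labels' protocols. The inner cells were separated from the outer layer by immunosurgery, which lyses outer cells. Fresh embryos were collected at E3.25, E3.75 and E4.0 (days after fertilisation). Others were cultured from E2.75 for 16 or 24 hours with 10 µM LY294002 (LY), an inhibitor of phosphoinositide 3-kinase (PI3K), or with its solvent DMSO. Polyadenylated RNA was reverse-transcribed from the 3′ end of transcripts, amplified, fragmented with Nextera XT and sequenced in pairs, per the labels' protocols. Cells were sequenced in 2 runs.

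The authors deposited 1 table of TPM values (transcript abundance scaled to a fixed total) with 170 columns, each matched to 1 sample by its title. Per the submitters' processing notes the tools were bcl2fastq 2.20.0, cutadapt 2.9, STAR 2.7.9a and RSEM 1.3.3 with genome build mm10. The notes give no settings, and the gene annotation is not given in the sources used here. TPM keeps no sequencing depth, so the depth of each cell is unknown, and the number of genes with a TPM of 1 or more served as the measure of library quality. TPM divides by transcript length while these libraries start at the 3′ end, so values compare 1 gene between samples and not different genes. Values of pseudogenes and of families with near-identical copies are uncertain, because reads can be shared between copies.

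The labels describe 186 samples. The 16 without a matching column were not analysed here. Of the 55513 lines of the table, 92 were external spike-in sequences and the other 55421 named a gene. Spike-in sequences were left out of all tests. In 2 experiments a pair of columns differed in title only by a suffix. The pair at E3.25 correlated at 0.824 across genes, above the highest correlation of either with another cell of that experiment (0.783), and was averaged as 1 cell. The pair in 24h LY correlated at 0.594, below the highest other value of 0.724, and was kept apart. This left 169 cells. No cell was removed, and no doublet caller was run because each sample is 1 picked cell.

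Cells of 1 embryo collection are not replicates. The replicate was the experiment, meaning the cells of 1 group that share a date label, and its value was the mean over its cells of log2(TPM + 1). This mean does not separate the share of cells that express a gene from its level in those cells. Each experiment pooled several litters, per the series' design text. By their date labels, all 16h experiments came later than all 24h and fresh ones. There were 18 experiment means in 7 groups, with 2 experiments for each fresh stage and 3 for each culture group. A difference is given on the log2(TPM + 1) scale, which understates the change of low genes. Genes were kept with a TPM of 1 or more in at least 25% of the cells of at least 1 group, which left 11680 genes. All 7 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend; 11 residual degrees of freedom), with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Every adjusted p of a gene below is from this limma model. The 9 comparisons were LY against DMSO at each culture time, the difference between these effects, the fresh stages against each other, the culture times of DMSO against each other, and each DMSO group against a fresh stage of near age.

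The LY and DMSO arms of a culture time carry the same 3 date labels, so the dates pair the arms. As a check, the correlation across genes of the deviations of same-date arms from their group means was 0.393, 0.121 and 0.317 at 16 hours and 0.231, 0.120 and 0.0732 at 24 hours. At 24 hours the third date's highest correlation with another date was 0.112. The fit with the date as a block (4 residual degrees of freedom) was an alternative.

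Of 32 gene lists, 31 had at least 5 tested genes. The list of totipotency and 2-cell genes did not, and was not tested. The lists held 707 symbols, of which 696 were in the table and 589 were tested. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with a correlation estimated from the data, with adjustment over the 31 lists. Camera is a test relative to all genes, so a list can be higher relative to the rest while its own median is near 0. The adjustment over a list alone used the same gene p-values.

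Shares of cells used a TPM of 10 or more for Nanog and Gata6, and for Sox2 and Sox17, with exact Clopper-Pearson 95% intervals. Intervals and upper limits for shares of 0 (3 counts) cover counting error only. LY and DMSO shares, marker scores (the mean log2(TPM + 1) of a list) and quality measures were compared by two-sided exact permutation of the 6 experiments. These permutations ignore the pairing of arms by date, so differences between dates add to their spread. With 3 against 3 the smallest p is 0.1, so these tests cannot reach 0.05. Correlations across cells used 100000 permutations. Cells were clustered on the 500 most variable genes into 6 clusters.

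The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to be later. For LY at each time and for E4.0 against E3.25, the rule took the 12 largest rises and 12 largest falls among genes past the threshold that had a mean of at least 2 in 1 of the groups and pointed the same way in every experiment. If fewer than 5 genes passed, the 10 smallest p were given as values. A set of 15 lineage and signalling genes was always given, as were the 4 members with the smallest p of each list past its test, except that 2 of these members are not given. Other comparisons used the 5 largest rises and falls. Gene positions are from GENCODE release M21 on mm10, which held 53569 of the table's lines and 11518 of the tested genes.

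Alternatives were other pseudocounts, the log of the mean TPM, no filter or a filter at 50% of cells, quantile normalization, the date block, an estimated correlation, a fit of only the groups compared, weights by the number of cells, each sequencing run alone, removal of cells of low detection, genes detected as a covariate, alike-titled cells or title prefixes kept apart, other share thresholds and cluster settings, and each experiment left out in turn. Rescaling TPM over nuclear protein-coding genes (21722), leaving out cells with Cdx2, and averaging the LY effect over both times were added after seeing the data. Cells with Cdx2 here means those at a TPM of 10 or more, 4 of 169, so cells with lower Cdx2 stayed in. On simulated data of the same size and spread with 100 genes changed by log2 2 and 100 by log2 4, 36% and 86% were recovered for LY at 16 hours with 7 false calls, and 31% and 91% at 24 hours with 9. For E4.0 against E3.25, 14% and 63% were recovered with 1 false call, and for 24h against 16h DMSO 27% and 88% with 2. The changed genes were not drawn from those of lowest mean expression, and simulated values had no floor at 0. Recovery of low genes is therefore not shown. Of 3 lists shifted as a whole in simulated data, by more than any list median given below for LY, 3 were called, with 0 others. The simulated genes varied independently of each other. The simulation therefore cannot show how many false list calls arise among genes that vary together.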

Results

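The series holds single-cell RNA sequencing of inner cells of the mouse blastocyst. These cells, the inner cell mass, become either epiblast, which forms the embryo proper, or primitive endoderm, which lines the yolk sac. Values were analysed for 169 cells in 18 experiments. There were 19 cells at E3.25, 22 at E3.75 and 14 at E4.0, each from 2 experiments. Cultured embryos gave 31 cells with DMSO and 31 with LY at 16 hours, and 28 with DMSO and 24 with LY at 24 hours, each from 3 experiments. An experiment held 3 to 18 cells. The depth of each cell is unknown, and 3806 to 10220 genes (median 6584) had a TPM of 1 or more. The mean number of such genes per cell was 6235 ± 223 (SD, n = 2 experiments) at E3.25, 6186 ± 262 at E3.75 and 7459 ± 315 at E4.0. The share of TPM from mitochondrially encoded genes ranged from 0.362% to 32.5% between cells. Experiments of a group are separate collection days, so errors are spreads between days.

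The fresh stages show how inner cells change as the lineages part. From E3.25 to E4.0, genes of the primitive endoderm rose most clearly, with 8 of 24 tested markers past the threshold over all genes and 14 when adjusted over the list alone. The list as a whole had an adjusted p = 6.88e-17, and adjusted p = 0.101 with an estimated correlation. Srgn, which encodes the proteoglycan serglycin, rose by 5.21 ± 0.41 (SE) on the log2 scale, from a mean log2(TPM + 1) of 0.29 ± 0.35 (SD, n = 2) to 5.50 ± 0.22 (adjusted p = 2.07e-07). Amn, a partner of the endocytic receptor cubilin, rose by 5.11 (adjusted p = 0.000165). The endoderm transcription factors Foxa2, Sox7 and Gata4 rose by 3.09, 2.03 and 3.22 (adjusted p = 7.43e-07, 0.000149 and 0.00942). The basement membrane gene Lama1 rose by 4.13, the collagen chaperone Serpinh1 by 4.25 and the transcription factor Foxq1 by 1.18 (adjusted p = 0.00657, 0.00158 and 0.00192). Srgn lies on chromosome 10 at 62493833 to 62527451 (ENSMUSG00000020077.14), Gata4 on chromosome 14 at 63198922 to 63271692 and Lama1 on chromosome 17 at 67697259 to 67822647.

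Several early or shared lineage genes did not pass the test between E3.25 and E4.0. Gata6, which acts early in primitive endoderm, differed by -0.38 ± 0.68 (SE), and Sox17 by 1.73 ± 0.65 (adjusted p = 0.873 and 0.245). Pdgfra, a receptor marking primitive endoderm, differed by 0.43, and the FGF receptors Fgfr1 and Fgfr2 by -2.14 and 1.31. The epiblast genes Nanog, Sox2, Fgf4, Klf4 and Esrrb differed by -1.82, 0.29, 0.91, 1.26 and -1.23. Pou5f1, a pluripotency factor, differed by -1.22, the ERK-induced phosphatase gene Dusp4 by 0.26, Foxo3 by -0.62 and the trophectoderm factor Cdx2 by -0.01. Adjusted p of these genes other than Gata6 and Sox17 lay between 0.362 and 0.995. The sign turned by mean TPM for Sox17 (14.2 at E4.0, 15.6 at E3.25), Pdgfra (5.02 and 15.5), Sox2 (18.1 and 21.8) and Cdx2 (0.23 and 0.22), while the others kept theirs. Nanog lies on chromosome 6 at 122707489 to 122714633 (ENSMUSG00000012396.12) and Gata6 on chromosome 18 at 11052064 to 11085635 (ENSMUSG00000005836.10).

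**Figure D1:**
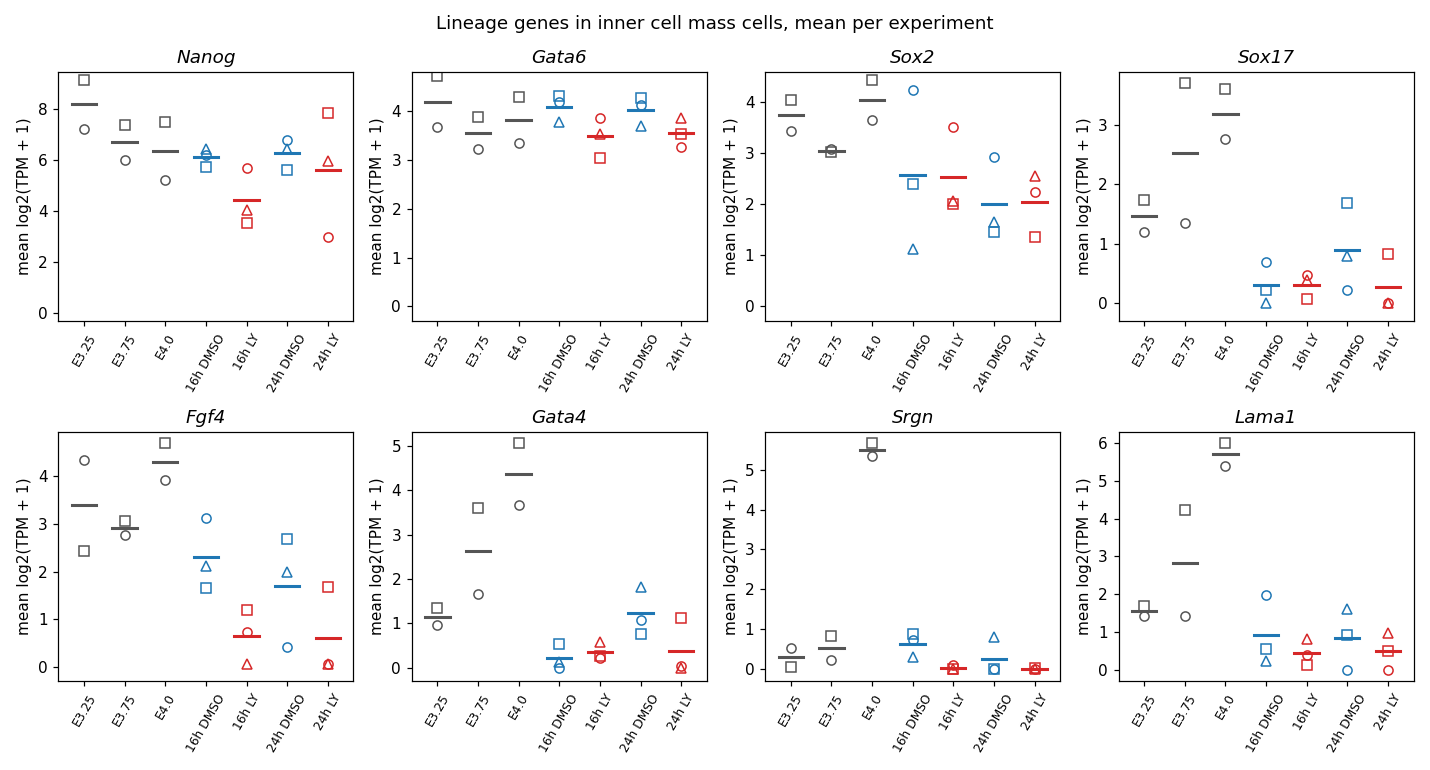
Mean log2(TPM + 1) of 8 lineage genes per experiment (points) with the group mean (bars) for the 3 fresh stages and the 4 culture groups. Srgn reached 5.50 at E4.0 against 0.29 at E3.25, and Nanog was 4.41 in 16h LY against 6.11 in 16h DMSO, a difference that did not pass the test.

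Other large rises by E4.0 were those of the NODAL antagonists Lefty1 and Lefty2 (4.83 and 4.53; adjusted p = 0.000327 and 0.000244), the secreted protease gene Htra1 (4.62), the hormone precursor gene Trh (4.42), the lactate dehydrogenase gene Ldha (4.82) and Gm28438 (5.01), an unprocessed pseudogene whose value is uncertain. Ppp1r1a, Wfdc2 and the phosphoglycerate mutase gene Pgam2 rose by 4.39, 4.36 and 4.25. The largest falls were those of Alppl2, an alkaline phosphatase gene (-5.91 ± 1.02; adjusted p = 0.00204), Cited1, a transcriptional co-regulator gene (-4.93; adjusted p = 0.00103), and Pemt, of phosphatidylcholine synthesis (-4.72; adjusted p = 0.0112). Crip2, the vitamin C synthesis gene Gulo, Tmem41b and Gpd1l fell, with differences of -4.46, -4.41, -4.41 and -4.18. The processed pseudogene Gm5612, Reep1, the betaine-homocysteine methyltransferase gene Bhmt, Cbr2 and Rflnb fell as well (-4.08, -4.04, -3.99, -3.99 and -3.89). In all, 195 of 11680 genes passed limma's threshold, 164 higher and 31 lower at E4.0, and 1502 had an unadjusted p under 0.05. The median over all genes was 0.20 higher at E4.0, where more genes were detected per cell. After quantile normalization 200 genes passed, 129 higher and 71 lower, and with genes detected as a covariate 204, 125 higher and 79 lower. A fit of only the 4 experiments compared called 0 genes, cells of run 1 alone gave 23 and cells of run 2 alone 420. Without the second E3.25 experiment 70 genes passed, without the first 127, and without the first E4.0 experiment 304. The count at an unadjusted p under 0.05 was 960 without the second E3.25 experiment, and the median over all genes was 0.13 without the second E4.0 experiment. Of 40 named genes past the threshold, 18 stayed past it in each of the 4 fits without 1 experiment, among them Srgn, Foxa2, Lefty1, Trh, Alppl2 and Cited1. Gata4, Lama1, Pemt, Gm5612, Pgam2, Wfdc2, Rflnb and Bad were lost in 3 of these fits (adjusted p up to 0.241), and Ldha, Pfkl, Dnmt3l, Psap and Gm28438 in all 4. Ppp1r1a, Bhmt, Cbr2, Gpd1l, Tmem41b, Aldoc, Hspg2 and Ifitm1 were lost in 2 and Reep1 in 1.

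Gene groups changed with the stage as well. Relative to all genes, 9 lists rose and 2 fell from E3.25 to E4.0 by camera, and none of the 31 passed with an estimated correlation. Primitive endoderm markers rose (median 2.09; adjusted p = 6.88e-17, and adjusted p = 0.101 with an estimated correlation). Genes of glycolysis, which breaks down glucose, rose with 4 of 20 past the threshold and 8 adjusted over the list alone (adjusted p = 3.51e-05; adjusted p = 0.283 with an estimated correlation). They were Pdk1 (2.40), Aldoc (1.81), Ldha (4.82) and Pfkl (2.93). Laminin and basement membrane genes rose with 4 of 20 past the threshold and 8 over the list alone (adjusted p = 4.89e-05; adjusted p = 0.542 with an estimated correlation), led by Nid2 (3.91) and, at a low level, Hspg2 (0.82). Formative or primed pluripotency genes rose with 2 of 9 past the threshold, Dnmt3l (3.62) among them, and 5 over the list alone, while Dnmt3a (1.80) and Otx2 (1.64) did not pass. The list's adjusted p was 3.51e-05, and adjusted p = 0.101 with an estimated correlation. Epiblast markers rose with 3 of 17, Enox1 (2.28), Morc1 (1.66) and Ifitm1 (1.95), and 4 over the list alone, with Zfp42 at 2.18. The list's adjusted p was 0.00285, and adjusted p = 0.585 with an estimated correlation. NODAL and BMP targets rose with 2 of 12, Lefty1 and Lefty2, and 3 over the list alone, while Nodal (0.78) and Foxh1 (2.32) did not pass over all genes. The list's adjusted p was 0.00402, and adjusted p = 0.585 with an estimated correlation.

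Lists of ribosomal proteins, mitochondrially encoded genes and oxidative phosphorylation also rose from E3.25 to E4.0 (medians 0.95, 1.95 and 0.96; adjusted p = 0.00472, 0.0119 and 0.0226). No member passed over all genes or over the list alone, and each had an adjusted p = 0.762 with an estimated correlation. Examples were Rpl35 (2.19), Rpl26 (2.24), Rps4x (2.16) and Rps24 (2.92), mt-Nd6, mt-Nd5, mt-Nd3 and mt-Nd2 (1.95, 1.97, 4.63 and 1.88), and Ndufa4, Ndufa1, Cox7b and Cox6c (3.84, 2.85, 4.17 and 2.91). The mitochondrial share of TPM was 3.04% and 10.8% in the E3.25 experiments and 16.1% and 14.3% in those of E4.0. Each of these lists was lost without the first E4.0 experiment (adjusted p = 0.541, 0.960 and 0.349), and oxidative phosphorylation with log2(mean TPM + 1) (adjusted p = 0.140). Without the second E3.25 experiment the ribosomal and oxidative phosphorylation lists turned to lower (adjusted p = 0.225 and 0.895), and without the first the mitochondrial list was lost (adjusted p = 0.876). The p53 and apoptosis list fell (median -0.20; adjusted p = 0.0271, and adjusted p = 0.762 with an estimated correlation) with 1 of 20 past the threshold, Bad (-3.59), a promoter of cell death, and 2 over the list alone. Perp (-3.15), Gadd45a (1.41) and Pmaip1 (1.01) did not pass over all genes. The lysosome and autophagy list under TFEB fell (median -0.22; adjusted p = 0.00472, and adjusted p = 0.585 with an estimated correlation) with 1 of 25, the lysosomal gene Psap (-2.73), and 1 over the list alone, while Rragd (-2.73), Sqstm1 (-2.03) and Map1lc3b (-1.34) did not pass. The p53 call was lost without the first E3.25 experiment or either E4.0 experiment (adjusted p = 0.175, 0.0852 and 0.0811). The other 20 lists had adjusted p from 0.0532, for PI3K AKT pathway components, to 0.807.

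E4.0 was also compared with E3.75, using the same 2 E4.0 experiments as above, so the comparisons are not independent. Srgn (4.97), the coagulation inhibitor gene Tfpi (4.62), Htra1 (4.53), Trh (4.27) and Gm28438 (4.82) had the largest rises (adjusted p = 4.22e-07, 2.85e-05, 0.000568, 3.34e-05 and 0.0391). The largest falls were those of Gm3183 (-4.10), the processed pseudogene Gm6166 (-4.02), Plac9b (-3.83), Reep1 (-3.16) and Crip2 (-3.16). Of these 10 genes, Srgn, Tfpi, Htra1 and Trh stayed past the threshold in each of the 4 fits without 1 experiment. Gm3183 and Reep1 were lost in all 4 (adjusted p from 0.116 to 0.327), Plac9b, Crip2 and Gm28438 in 3 (adjusted p up to 0.454, 0.363 and 0.590) and Gm6166 in 2 (adjusted p up to 0.211). Primitive endoderm markers rose with 7 of 24 past the threshold and 12 over the list alone (median 1.74; adjusted p = 1.98e-14, and adjusted p = 0.105 with an estimated correlation). Lists of glycolysis (1 of 20; 8 over the list alone), laminin and basement membrane (3 of 20; 7), formative or primed pluripotency (2 of 9; 6), cholesterol synthesis (1 of 23; 2), epiblast markers (3 of 17; 3), hypoxia targets (0 of 15; 6), NODAL and BMP targets (2 of 12; 3) and the unfolded protein response (0 of 20; 2) rose as well. Their adjusted p was 4.24e-06, 9.58e-06, 9.62e-06, 0.00305, 0.00626, 0.00626, 0.0153 and 0.000449. With an estimated correlation the adjusted p = 0.186, 0.321, 0.105, 0.597, 0.582, 0.193, 0.582 and 0.507. Ribosomal proteins fell relative to all genes (adjusted p = 0.0304; adjusted p = 0.846 with an estimated correlation), with a median of -0.00 and a mean of 0.16, so the mean and the test differ in sign. That list turned to higher after quantile normalization (adjusted p = 0.654) and was lost without the first E3.75 or second E4.0 experiment (adjusted p = 0.846 and 0.818) and after rescaling TPM over nuclear protein-coding genes (adjusted p = 0.0595). In all, 165 genes passed, 157 higher and 8 lower, and 1108 had an unadjusted p under 0.05, with a median over all genes of 0.29. More genes were detected per cell at E4.0 (7459) than at E3.75 (6186), which can tilt this balance. Without the first or second E3.75 experiment 51 and 70 genes passed, and without the first E4.0 experiment 278. A fit of only these groups called 0 and quantile normalization 105. Without the first E3.75 experiment the epiblast, NODAL and BMP, hypoxia and cholesterol lists were lost (adjusted p = 0.268, 0.343, 0.0685 and 0.0662). Without the second E4.0 experiment the epiblast and NODAL and BMP lists were lost (adjusted p = 0.164 and 0.120), and without the first the cholesterol list (adjusted p = 0.0794).

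Between E3.25 and E3.75 no single gene passed limma's threshold, and 536 had an unadjusted p under 0.05 (863 without the first and 339 without the second E3.25 experiment). Without the first E3.25 experiment 9 genes passed and without the first E3.75 experiment 4. The smallest p belonged to Gm15892 (-1.26), Gm49957 (-1.45), the mitochondrial tRNA gene mt-Tn (4.91), the lens crystallin gene Crygc (2.73) and the autophagy gene Map1lc3a (-2.97), with adjusted p from 0.535 to 0.781. Relative to all genes, lists of ribosomal proteins (median 0.72), oxidative phosphorylation (0.51), primitive endoderm markers (0.45) and ATF4 targets of amino acid stress (0.58) rose, and trophectoderm markers fell (-0.41). The adjusted p was 8.05e-12, 0.000127, 0.0251, 0.0303 and 0.0303, and for each the adjusted p = 0.815 with an estimated correlation. No member passed over all genes or over the list alone. With log2(mean TPM + 1) all but the ribosomal list were lost (adjusted p from 0.0564 to 0.238). Without the second E3.25 experiment the ribosomal, oxidative phosphorylation and ATF4 lists were lost (adjusted p = 0.679, 0.798 and 0.206), ATF4 also without the first experiment of either stage (adjusted p = 0.0650 and 0.546), primitive endoderm without the first E3.25 or second E3.75 experiment (adjusted p = 0.205 and 0.824), and trophectoderm without any 1 of the 4 (adjusted p from 0.0555 to 0.202).

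Embryos cultured with LY address how gene expression in inner cells differs under this inhibitor. PI3K activity was not measured in these data, so effects of LY other than on PI3K were not separated. After 16 hours, genes of cholesterol synthesis were lower with LY in 23 of 23 tested members (median -0.80), against a median over all genes of -0.33. Insig1 and Hmgcs1, which regulate and start the pathway, differed by -1.75 ± 0.72 and -1.42 ± 0.68 (SE, n = 3 experiments each), and the sterol enzymes Msmo1 and Sc5d by -1.33 and -1.15. Fatty acid synthesis genes were lower in 16 of 16 (median -0.62), among them the desaturases Scd1 (-2.25) and Scd2 (-2.51), the elongase Elovl5 (-1.62) and the fatty acid synthase Fasn (-1.98). Both lists fell relative to all genes by camera (adjusted p = 0.00570 and 0.00639), and both were lost with an estimated correlation (adjusted p = 0.790). No gene of either list passed over all genes or adjusted over the list alone. Both lists passed without each date in turn, with adjusted p up to 0.0147 and 0.0378. Of 10000 random lists matched on expression, 0.2% had a median as low as the cholesterol list and 12.2% as low as the fatty acid list, but 7 of 31 lists lay outside the middle 95% of their random lists, so the test excludes little. Scd1 lies on chromosome 19 at 44394455 to 44407879.

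Trophectoderm markers, genes of the outer layer, also fell with LY at 16 hours (14 of 14 below 0; median -0.67; adjusted p = 0.0222, and adjusted p = 0.790 with an estimated correlation), with Cdx2 at -0.80, Ptges at -2.48, Tspan8 at -1.47 and Lgals3 at -1.55. Cdx2 reached a TPM of 10 in 1 of 31 DMSO cells and 0 of 31 LY cells, which allows a share of up to 9.68%. At a TPM of 1 or more it was detected in 8 of 31 DMSO cells and 1 of 31 LY cells. At 24 hours the order turned, with 2 of 28 DMSO cells and 5 of 24 LY cells. Without the first date, whose DMSO arm held 3 cells, the trophectoderm list was lost (adjusted p = 0.362). Ribosomal protein genes rose relative to all genes (median 0.10; adjusted p = 4.40e-07, and adjusted p = 0.790 with an estimated correlation), among them Rpl12 (0.63), Rps10 (0.53), Rpl13 (0.60) and Rps13 (0.50). The p53 and apoptosis list rose relative to all genes (adjusted p = 0.0222, and adjusted p = 0.790 with an estimated correlation), with a median of -0.04, a mean of 0.00 and 14 of 20 members above the median of all genes. Its members with the smallest p were Btg2 (1.12), a brake on proliferation, Gadd45a (-0.91), Bad (-0.70) and Aen (-0.79). No member of these lists passed over all genes or over the list alone. Of 10000 random lists matched on expression, 94.3% had a lower median than the ribosomal list (0.10, against -0.01 for its matched lists). Expression level may therefore account for the ribosomal call. For the trophectoderm and p53 lists 2.34% and 99.5% of matched lists had a lower median, though, as for the lipid lists, this test excludes little. Quantile normalization ended the ribosomal and p53 calls (adjusted p = 0.213 and 0.0688), and the p53 list was lost without the first or second date (adjusted p = 0.102 and 0.307).

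No single gene passed limma's threshold for LY at 16 hours (0 of 11680, and 0 with the date block). At an unadjusted p under 0.05 there were 641 genes, 48 higher and 593 lower, against 584 expected by chance, and 1413 with the block. Fewer genes were detected with LY, and the share of higher genes among these, 7.49%, was 47.6% after quantile normalization, a scaling that itself sets the balance (median over all genes 0.01), and 48.3% with genes detected as a covariate. Without date 1 there were 428 genes, 13.6% of them higher. The smallest p was that of Prl3b1, a placental hormone of the trophoblast (-1.12 ± 0.19; adjusted p = 0.0701), followed by the mitochondrial tRNA gene mt-Tk (2.84), Allc (-1.91), Gm48222 (-2.29), Tnfsf13b (-1.28), Usp46 (-1.19), Lyrm4 (-1.33), the desaturase Scd3 (-2.06), Mir3063 (-3.07) and Parp8 (-2.18). Each of these 10 pointed the same way on 3 of 3 dates, with adjusted p up to 0.393. Nanog was 4.41 ± 1.12 (SD, n = 3) with LY and 6.11 ± 0.35 with DMSO, a difference of -1.70 ± 0.94 (SE), lower on 3 of 3 dates (adjusted p = 0.854). Fgf4, the growth factor made by epiblast cells, differed by -1.64 and Dusp4 by -1.39, both lower on 3 of 3 dates. Gata6 differed by -0.61, Pdgfra by -1.10, Sox2 by -0.05, Gata4 by 0.13, Sox17 by 0.00, Fgfr1 by -0.27, Fgfr2 by 0.10, Pou5f1 by 0.36, Klf4 by 0.42, Esrrb by 0.58 and Foxo3 by 0.32. In mean TPM the sign turned for Esrrb (114 with LY, 151 with DMSO), Gata4 (0.78 and 1.27) and Sox17 (0.49 and 0.52), while the other genes of this set kept theirs. Of the other 26 lists, adjusted p ran from 0.0519, for LIF STAT3 targets, to 0.979. With the date block 7 lists passed, adding LIF STAT3 targets (higher) and DNA methylation and chromatin genes (lower), each at an adjusted p = 0.0283. The block was run with the preset correlation, and without it these lists had an adjusted p = 0.790 and 0.857 with an estimated correlation.

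After 24 hours with LY, oxidative phosphorylation genes fell relative to all genes, with 39 of 45 members below 0 (median -0.84, all genes -0.20; adjusted p = 0.00399, and adjusted p = 0.881 with an estimated correlation). The subunit genes Atp5o (-2.99 ± 0.82 SE), Ndufa2 (-2.10), Atp5c1 (-2.18) and Cox8a (-1.56) had the smallest p of the list. Ribosomal protein genes fell with 63 of 74 below 0 (median -0.68; adjusted p = 0.00669, and adjusted p = 0.881 with an estimated correlation), among them Rpl27 (-1.35), Rpl21 (-1.97) and Rps9 (-1.49). The p53 and apoptosis list rose (median 0.19; adjusted p = 0.00399, and adjusted p = 0.881 with an estimated correlation), with Phlda3 at 1.24, Btg2 at 1.02, Bmf at 0.76 and Bad at -1.83. PI3K AKT pathway components rose (median 0.17; adjusted p = 0.0136, and adjusted p = 0.881 with an estimated correlation), with Rheb, an activator of mTOR, at 1.18, Gsk3a at 1.19, Pik3cb at 0.36 and Mtor at -0.94. No member passed over all genes or over the list alone. With log2(mean TPM + 1) the oxidative phosphorylation, p53 and PI3K lists were lost (adjusted p = 0.203, 0.0728 and 0.0728). Without the first date the oxidative phosphorylation, ribosomal and PI3K lists were lost (adjusted p = 0.146, 0.663 and 0.146), without the second the ribosomal and PI3K lists (adjusted p = 0.0934 and 0.0693), and without date 3 the p53 list (adjusted p = 0.111).

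No single gene passed limma's threshold for LY at 24 hours, with or without the date block. At an unadjusted p under 0.05 there were 615 genes, 84 higher and 531 lower, and 1334 with the block, and 1 gene passed without date 3. The share of higher genes, 13.7%, was 55.6% after quantile normalization, where the median over all genes is set to 0.03, and 60.4% with genes detected as a covariate. Without date 1 the count was 312 and without date 3 546, with 20.2% and 28.2% of genes higher. The median over all genes, -0.20, was -0.31 without date 2 and -0.11 without date 3. The smallest p were those of Gm49957 (-1.35), Gm6851 (-3.30), the thioesterase gene Acot13 (-3.17), the mitochondrial import gene Timm10 (-3.87), Rfc3 of DNA replication (-2.49), Cck (-1.30), Pin4 (-3.82), Gm5612 (-2.90), the ATP synthase gene Atp5md (-3.60) and the mitochondrial protease gene Lonp1 (-2.06). Each of these was lower on 3 of 3 dates, with adjusted p from 0.327 to 0.899. Nanog differed by -0.68 ± 0.94 (SE), Gata6 by -0.47, Sox2 by 0.04, Fgf4 by -1.09, Gata4 by -0.84, Sox17 by -0.63, Pdgfra by -1.30, Fgfr1 by -0.10, Fgfr2 by -0.03, Pou5f1 by -0.65, Klf4 by -0.50, Esrrb by -0.14, Dusp4 by -0.07, Cdx2 by 0.29 and Foxo3 by 0.35. By mean TPM the sign turned for Nanog (187 with LY, 100 with DMSO) and Gata6 (28.6 and 25.7). It also turned for Fgfr1, Fgfr2, Klf4, Esrrb and Dusp4, while the other genes of this set kept theirs. Cholesterol synthesis, fatty acid synthesis and trophectoderm lists did not pass at 24 hours (adjusted p = 0.310, 0.222 and 0.813), though Fabp3 (-3.18), a fatty acid binding protein of the trophectoderm list, passed over its list alone. The other 27 lists had adjusted p from 0.0857, for FOXO target genes, to 0.960. With the date block 8 lists passed, adding primitive endoderm markers, epiblast markers and ATF4 targets (lower) and FOXO targets (higher), at adjusted p = 0.0420, 0.0338, 0.0387 and 0.0387. These calls rest on the preset correlation, and without the block each of the 4 had an adjusted p = 0.881 with an estimated correlation.

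The LY effect differed between the culture times for 3 lists. Ribosomal proteins, oxidative phosphorylation and ATF4 targets were lower at 24 hours relative to 16 hours (medians of the difference -0.66, -0.51 and -0.25; adjusted p = 7.18e-10, 0.000178 and 0.0207), each with an adjusted p = 0.891 under an estimated correlation. No gene differed by limma (0, and 291 at an unadjusted p under 0.05; 0 and 707 with the block). The smallest p were those of Allc (2.23), mt-Tk (-3.07), Prl3b1 (1.03), Eif5 (3.32) and Parp8 (2.55). The ATF4 call was lost without the second 16h date or 24h date 2 or 3 (adjusted p = 0.143, 0.0596 and 0.217), and with log2(mean TPM + 1) (adjusted p = 0.375).

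Nanog and Gata6 are seen together in inner cells before the lineages part. At a TPM of 10 or more, both were detected in 15 of 19 cells at E3.25 (78.9%, 95% interval 54.4 to 93.9%), 11 of 22 at E3.75 and 8 of 14 at E4.0. In culture both were detected in 23 of 31 cells with DMSO (74.2%, 55.4 to 88.1%) and 15 of 31 with LY (48.4%, 30.2 to 66.9%) at 16 hours, and in 18 of 28 (64.3%) and 11 of 24 (45.8%) at 24 hours (exact permutation p = 0.2 and 0.3). The difference in means over experiments was -20.2 percentage points at 16 hours, -6.52 without date 2 and -5.19 at a TPM of 50, and -21.8 at 24 hours, -34.2 without date 2 and -8.84 at a TPM of 50. Cells with Gata6 alone numbered 1 of 31 with DMSO and 6 of 31 with LY at 16 hours, with means over experiments of 1.85 ± 3.21% and 18.1 ± 9.82% (SD, n = 3). That difference of 16.3 points was 5.56 at a TPM of 1 and 0 at a TPM of 50. LY was higher on 3 of 3 dates (two-sided exact permutation p = 0.1, the smallest possible, and 0.711 adjusted over 16 tests). At 24 hours Gata6 alone was seen in 1 of 28 cells with DMSO and 2 of 24 with LY. That difference in means was 6.49 points, and -4.55 without date 1, with LY higher on 1 date and lower on 1. Cells with neither gene numbered 0 of 31 with DMSO, which allows up to 9.68%, and 4 of 31 with LY at 16 hours, and 0 of 28 (up to 10.7%) and 4 of 24 at 24 hours. The difference in means for neither gene was 12.7 points at 16 hours, 4.76 at a TPM of 1, 36.7 at a TPM of 50 and 8.33 without date 2. At 24 hours it was 20.95, 0 at a TPM of 1, -1.05 at a TPM of 50 and 10 without date 1. Sox2 and Sox17, markers of the parted lineages, reached a TPM of 10 together in 4 of 19 cells at E3.25, 5 of 22 at E3.75 and 5 of 14 at E4.0 (35.7%, 12.8 to 64.9%). In culture they did so in 2 of 28 24h DMSO cells, 0 of 24 24h LY cells, which allows up to 12.5%, and 0 of 31 cells in each 16h arm, which allows up to 9.68% each. At 16 hours Sox2 reached it alone in 10 of 31 and 13 of 31, while the difference in means over experiments was -5.93 points, 9.29 without date 1 and -20.6 without date 3. None of these 16 share differences passed adjustment, and fewer genes were detected per cell with LY.

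**Figure D2:**
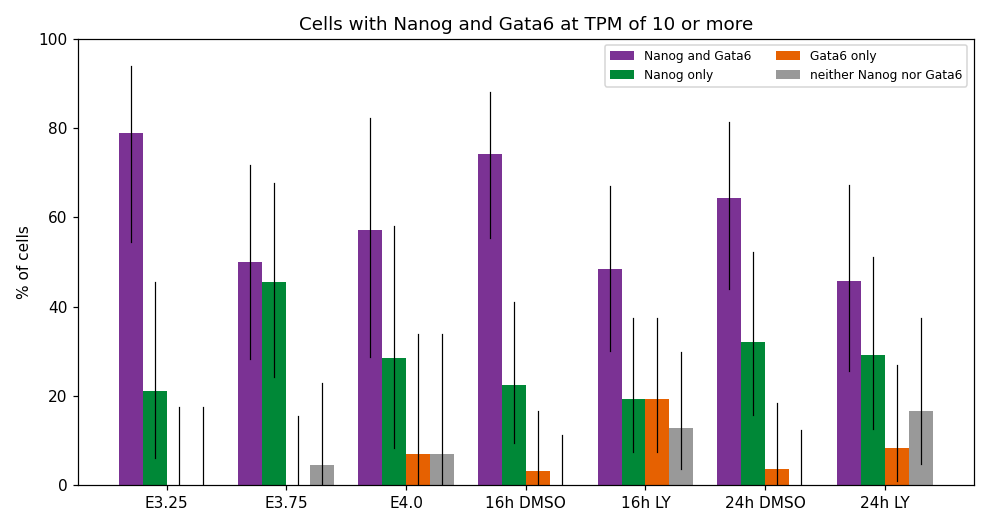
Share of cells (%) per group with Nanog and Gata6, Nanog alone, Gata6 alone or neither at a TPM of 10 or more, with exact 95% binomial intervals (lines) that cover counting error only. Both genes were detected in 74.2% of 16h DMSO cells and 48.4% of 16h LY cells, with overlapping intervals.

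Marker scores were lower with LY for each lineage, as was the median over all genes (-0.33 at 16 hours and -0.20 at 24 hours), with fewer genes detected per cell. The epiblast score was 2.66 ± 0.49 (SD, n = 3) with LY and 3.26 ± 0.69 with DMSO at 16 hours, and 2.53 ± 0.64 and 3.23 ± 0.65 at 24 hours. The primitive endoderm score was 1.39 ± 0.25 and 1.90 ± 0.55 at 16 hours and 1.36 ± 0.33 and 1.90 ± 0.49 at 24 hours, and the trophectoderm score 2.31 ± 0.44 and 3.23 ± 1.21, then 1.74 ± 0.32 and 2.14 ± 0.22. Each was lower with LY on 3 of 3 dates, with exact permutation p of 0.2 or 0.3 (adjusted p = 0.3 over 6 tests). This permutation ignores the pairing of arms by date, and no paired test of the scores was run. The fresh stages had primitive endoderm scores of 2.00 ± 0.15, 2.42 ± 0.59 and 4.24 ± 0.16 (SD, n = 2) at E3.25, E3.75 and E4.0. Across cells, Nanog and Gata6 levels showed no correlation past the threshold in any of the 7 groups, with an adjusted Spearman permutation p of 0.588 in each. In 16h LY, Pearson's r was 0.40 (permutation p = 0.0263, adjusted 0.184) and Spearman's rho 0.20 (permutation p = 0.274). Without the 2 cells farthest from the median r was 0.42, and the mean rho within experiments was 0.03. Within sequencing runs, rho in 16h LY was 0.04 in run 1 and 0.62 in run 2.

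Fewer genes were detected per cell with LY. The means were 6832 ± 1306 (SD, n = 3) with LY and 8084 ± 1655 with DMSO at 16 hours, and 5439 ± 918 and 6454 ± 648 at 24 hours (exact permutation p = 0.4 and 0.2). LY was lower on 6 of 6 dates, by a mean of -1134 (SD 532; exact sign-flip p = 0.0313 over 64 flips, a test chosen after the values were seen). At a TPM of 10 or more, LY was lower on 3 of 3 dates at 16 hours (means 3757 and 4386) and 2 of 3 at 24 hours (3412 and 3832), with 3910 genes with LY and 3848 with DMSO on 24h date 2. Within run 1 the mean difference was -1285 ± 311 (SE over 6 dates), and within run 2 it was -1099 ± 204. The mitochondrial share of TPM was 10.4 ± 2.49% with LY and 12.8 ± 1.83% with DMSO at 16 hours, and 5.74 ± 1.75% and 6.61 ± 4.38% at 24 hours.

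**Figure D3:**
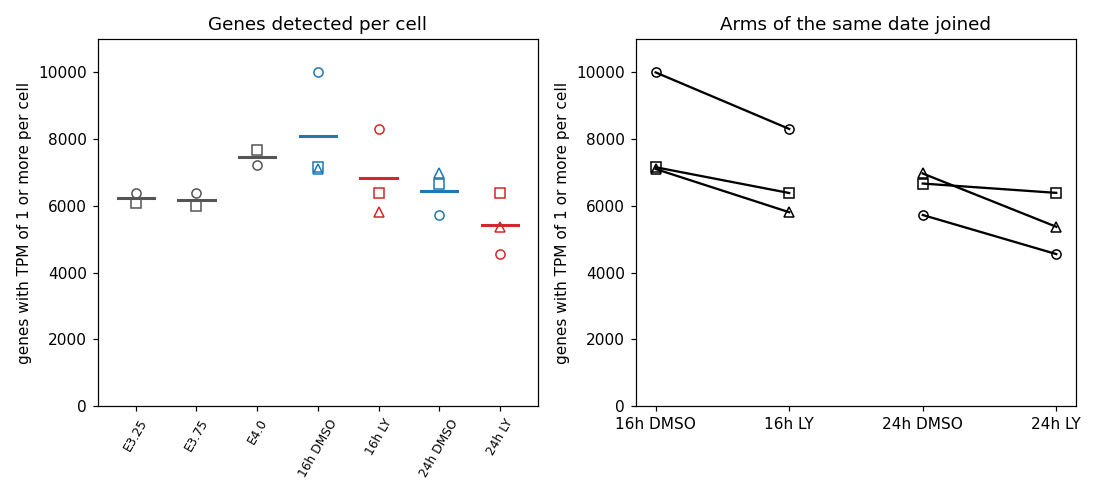
Number of genes with a TPM of 1 or more per cell, as the mean of each experiment (points) and of each group (bars), with lines joining the LY and DMSO arms of a date. LY lies below DMSO on 6 of 6 dates.

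Culture with DMSO alone shows the change over time without the inhibitor, though all 16h dates came later than all 24h dates. The same 16h DMSO experiments also served in the comparisons with LY at 16 hours and with fresh E3.25 cells. Results that recur across these comparisons, such as those of Prl3b1 and Gm48222, are therefore not independent. From 16 to 24 hours, 1 gene passed, Prl3b1, which fell by 1.35 (adjusted p = 0.00455). It was lost without the first or second 24h date, after quantile normalization, with genes detected as a covariate, in each run alone and in a fit of only these groups (0 genes in each). Without 16h date 2 or 3 there were 5 and 3 genes. The next were Allc (-2.04), the mitochondrial tRNA gene mt-Tm (-4.78), Gm48222 (-2.64) and Gm28438 (-5.05), each at an adjusted p = 0.0617. At an unadjusted p under 0.05 there were 1268 genes, 72 higher and 1196 lower, with a median over all genes of -0.29, while genes detected per cell went from 8084 to 6454. The share of higher genes, 5.68%, was 40.8% after quantile normalization, which sets the median over all genes to 0.05, and 63.3% with genes detected as a covariate, and without 16h date 1 the median was -0.02 with 770 genes, 26.9% of them higher. Without 24h date 1 there were 612 genes, 12.9% of them higher, and without 16h date 3 the median was -0.45. Mitochondrially encoded genes fell (15 of 15 below 0; median -3.29; adjusted p = 7.21e-11, and adjusted p = 0.948 with an estimated correlation), with 0 past the threshold over all genes and 13 over the list alone. Trophectoderm markers fell (14 of 14 below 0; median -0.81; adjusted p = 0.00409, and adjusted p = 0.948 with an estimated correlation), with 0 and 1. Laminin and basement membrane genes and LIF STAT3 targets rose relative to all genes (medians 0.19 and 0.29; adjusted p = 0.0252 and 0.0438), with 0 and 0 each. Each of these also had an adjusted p = 0.948 with an estimated correlation. Both were lost with log2(mean TPM + 1) (adjusted p = 0.128 each) and without cells with Cdx2 (adjusted p = 0.0503 each), and LIF after quantile normalization (adjusted p = 0.136). The trophectoderm call was lost without 16h date 1 or 24h date 3 (adjusted p = 0.168 and 0.156), the laminin call without 16h date 1, 16h date 3 or 24h date 3 (adjusted p from 0.102 to 0.285), and the LIF call without 4 of the 6 dates (adjusted p from 0.0599 to 0.277).

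Against fresh E3.25 cells, all collected before the 16h dates, 16h DMSO cells had 6 genes past the threshold. Prl3b1 (1.45), Rab26os (3.74), Gm48222 (3.13), the unprocessed pseudogene Gm12616 (6.29) and mt-Tm (5.26) rose, and Gm15892 fell by 1.21 (adjusted p = 0.00906, 0.0408, 0.0444, 0.0444, 0.0499 and 0.0499). Without the second E3.25 experiment 0 genes passed, without the first 52, without 16h date 1, 2 or 3 there were 1, 2 and 3, and a fit of only these groups called 49. None of the 6 passed in all 5 of these fits without 1 experiment. At an unadjusted p under 0.05 there were 1599 genes, 1328 higher, with a median over all genes of 0.32, and 797 genes without the second E3.25 experiment. The share of higher genes, 83.1%, was 44.5% after quantile normalization, which sets the median over all genes to -0.04, and 29.6% with genes detected as a covariate, and without 16h date 1, of 3 DMSO cells, 61.3% were higher and the median was 0.04. Relative to all genes, 3 lists rose, namely mitochondrially encoded genes (median 3.17; 0 of 15 past the threshold, 11 over the list alone), ribosomal proteins (1.12; 0 of 74, 8) and ATF4 targets (1.27; 0 of 24, 5), and 11 fell. For the 3 rises the adjusted p was 5.96e-06, 5.96e-06 and 0.00891, and the adjusted p = 0.562, 0.595 and 0.626 with an estimated correlation. LIF STAT3 targets fell most clearly (11 of 14 below 0; 0 past the threshold, 1 higher and 5 lower over the list alone; adjusted p = 2.38e-07, and adjusted p = 0.327 with an estimated correlation). Epiblast markers (median -0.99; adjusted p = 7.45e-05), laminin and basement membrane genes (-0.44; 0.00210), formative or primed pluripotency (-0.51; 0.00265), FGF ERK targets (-0.12; 0.0116), naive pluripotency (-0.42; 0.0146), ribosome biogenesis and MYC targets (-0.21; 0.0146), PI3K AKT components (-0.16; 0.0180), G1/S genes (-0.17; 0.0275), primitive endoderm markers (-0.09; 0.0415) and NODAL and BMP targets (-0.13; 0.0447) followed. No list of the 14 passed with an estimated correlation (smallest adjusted p = 0.327). Over the list alone 1 FGF ERK and 1 formative member passed as lower, and 0 of the other falling lists. The MYC list had a mean of 0.06, against its median and test. With log2(mean TPM + 1) the FGF ERK, laminin, NODAL and BMP, PI3K and primitive endoderm lists were lost (adjusted p from 0.0712 to 0.582), and after quantile normalization the NODAL and BMP and primitive endoderm lists (adjusted p = 0.0642 and 0.0694). Without the second E3.25 experiment the ribosomal list turned to lower (adjusted p = 0.946), and the ATF4, laminin, naive, MYC, PI3K, G1/S and primitive endoderm lists were lost (adjusted p from 0.0545 to 0.224). Without the first, the mitochondrial and NODAL and BMP lists were lost (adjusted p = 0.151 and 0.221), and primitive endoderm (adjusted p = 0.0524). Without 16h date 1 the naive, MYC and primitive endoderm lists were lost (adjusted p = 0.0892, 0.0503 and 0.0945), without date 2 the NODAL and BMP list (adjusted p = 0.0640), and without date 3 the G1/S, NODAL and BMP and primitive endoderm lists (adjusted p = 0.0621, 0.123 and 0.0895).

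Against fresh E3.75 cells, 24h DMSO cells had 0 genes past limma's threshold and 370 at an unadjusted p under 0.05 (619 without the first E3.75 experiment). Without the first E3.75 experiment 5 genes passed and without the second 1. The smallest p were those of Crygc (-2.71), Gm7079 (-3.40), Gm49957 (1.33), Dhrs3 of retinoid metabolism (-1.12) and Tmem45a (-0.76). Epiblast markers were lower in culture (15 of 17 below 0; median -0.93; adjusted p = 3.06e-06), as were FGF ERK targets (14 of 16; -0.38; adjusted p = 2.66e-05), primitive endoderm markers (17 of 24; -0.33) and NODAL and BMP targets (10 of 12; -0.73), the last pair each at an adjusted p = 5.86e-05. With an estimated correlation none of the 31 lists passed (smallest adjusted p = 0.199). Formative or primed pluripotency (-0.62; adjusted p = 0.000235), LIF STAT3 targets (-0.39; adjusted p = 0.00469), mitochondrially encoded genes (-0.76; adjusted p = 0.0124) and laminin genes (-0.30; adjusted p = 0.0197) fell too, while ATF4 targets (0.48; adjusted p = 0.0124) and lysosome and autophagy genes (0.44; adjusted p = 0.0197) rose. These too did not pass with an estimated correlation (adjusted p of 0.199 or more). With log2(mean TPM + 1) the laminin, LIF, mitochondrial and primitive endoderm lists were lost (adjusted p = 0.344, 0.0586, 0.0643 and 0.154), the mitochondrial list also after quantile normalization (adjusted p = 0.135). Over the list alone 1 epiblast, 1 LIF and 1 NODAL and BMP member passed. Without the second E3.75 experiment the primitive endoderm, LIF, laminin, ATF4 and lysosome lists were lost (adjusted p = 0.421, 0.828, 0.994, 0.441 and 0.0560), the lysosome list also without the first (adjusted p = 0.226), and the mitochondrial list turned to higher without the first 24h date or the first E3.75 experiment (adjusted p = 0.603 and 0.152). Without the first 24h date the ATF4, laminin and lysosome lists were lost (adjusted p = 0.0939, 0.183 and 0.206), and without the second the laminin list (adjusted p = 0.0968).

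Genes that changed between E3.25 and E4.0 were then followed in culture. These lists were chosen on the fresh libraries of this series, so only their direction in the culture libraries is new. Their camera p-values were adjusted only over the list of higher and the list of lower genes within each comparison. They are thus less strictly adjusted than those of the fixed lists above. The 164 genes higher at E4.0 were higher in 24h than in 16h DMSO cells only relative to all genes (86 above 0 and 74 below; median 0.01, all genes -0.29; adjusted p = 0.000107, and adjusted p = 0.263 with an estimated correlation). They were lower in 24h DMSO than at E3.75 relative to all genes (72 above 0 and 89 below; median -0.03, all genes 0.10; adjusted p = 3.44e-06, and adjusted p = 0.0880 with an estimated correlation). The 31 genes lower at E4.0 were higher in 24h DMSO than at E3.75 (24 of 31 above 0; median 0.90; adjusted p = 5.53e-07, and adjusted p = 0.0285 with an estimated correlation). With LY neither list passed at 16 hours (adjusted p = 0.0870 and 0.593) or at 24 hours (adjusted p = 0.282 and 0.139).

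Cells were also grouped into 6 clusters, given by number because none held 3 markers of 1 lineage among its 10 leading genes. Cluster 5 held 10 cells, with the primitive endoderm markers Srgn and Amn among its leading genes and median primitive endoderm and epiblast scores of 5.22 and 4.89, both the highest of the 6 clusters. Of its cells 8 came from E4.0, 1 from 16h DMSO and 1 from 24h DMSO. Cluster sizes were not compared between groups, since the genes that define the clusters differ between the groups.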

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

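The tests of LY averaged over both culture times, with their swaps of arms, were chosen only after the LY results had been seen.

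The LY effect differed between the culture times for 3 lists, by camera on the difference of the effects. Ribosomal protein genes had a median difference from DMSO of 0.10 at 16 hours and -0.68 at 24 hours (adjusted p of the difference between times = 7.18e-10). Oxidative phosphorylation genes had medians of -0.33 and -0.84 (adjusted p = 0.000178), and ATF4 targets, which answer amino acid stress, -0.19 and -0.68 (adjusted p = 0.0207). With an estimated correlation none passed (adjusted p = 0.891 each). The ribosomal and oxidative phosphorylation calls passed without each of the 6 dates in turn, while ATF4 was lost without 16h date 2 (adjusted p = 0.143), 24h date 2 (adjusted p = 0.0596) or 24h date 3 (adjusted p = 0.217), and with log2(mean TPM + 1) (adjusted p = 0.375). The spread between dates enters the statistic of each gene, but camera's p at the preset correlation compares list members with other genes. It does not measure how a list as a whole varies from date to date. All 16h dates came later than all 24h dates, so a shift shared by the dates of a culture time was not separated from time. No explanation was tested.

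Spike-in sequences, which are synthetic RNAs of known amount, carried signal in some cells although no source used here says how they were added. Their highest share of TPM in a cell was 0.296%, and the medians per experiment ran from 0% to 0.0628%. They were left out of all tests.

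Relabelling shows how large such results can be when the same 6 experiments are grouped otherwise. Each side of another split still holds more experiments of 1 group than of the other. Part of the real difference therefore stays in these counts, and they are no reference without the treatment. For LY at 16 hours, 5 of the 10 splits of the 6 experiments gave as many genes at an unadjusted p under 0.05 (641 in the real split, 2129 in the highest other), and 1 of 10 as many lists (5 against 4). For LY at 24 hours, 3 of 10 splits gave as many genes (615 against 1166) and 3 of 10 as many lists (4 against 4). For 24h against 16h DMSO these were 1 of 10 for genes (1268 against 892) and 3 of 10 for lists (4 against 6). With 10 splits the share cannot fall under 0.05. At 16 hours the 4 splits that set date 1 apart from another date gave 654 to 2129 genes, each above the real one, which points to a structure by date. At 24 hours such splits gave 711, 1166, 353 and 299 genes, on both sides of the real 615. Among splits that part all 3 date pairs, the others gave 149, 167 and 141 genes at 16 hours against 641, and 410, 454 and 198 at 24 hours against 615. With the date block the counts were 1413 and 1334, with 0 genes past the threshold by limma.

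For LY averaged over both times with the date block, 1 of 32 swaps of the arms within dates gave as many genes at an unadjusted p under 0.05, the real one (2076, highest other 1788 with the arms of 24h date 2 swapped). For genes that pointed the same way on all 6 dates, each swap was given the larger of its counts lower and higher. By this measure 1 of 32 gave as many (1017 lower in the real one, highest other 929). For lists 6 of 32 gave as many (6, highest other 7). A share of 1 in 32 is the smallest these swaps can give. The test was chosen after LY cells had been seen to have fewer genes detected on 6 of 6 dates, so it is no independent evidence against chance. No gene passed limma's threshold in this test (0 with and 0 without the block).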

How the results depend on the processing

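Rescaling TPM, leaving out cells with Cdx2 and averaging LY over both times were chosen only after the data had been seen. The cause of each change below was not tested, unless stated.

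Named genes past the threshold stayed past it in 824 tests under an alternative and lost it in 309, with 0 reversed. Gene list calls were kept in 459, lost in 174 and reversed in 6. Counts of genes stayed within 1.5 times in 126 and moved in 62, counts of lists in 63 and 27, and untested values stayed within their spread in 119 and moved in 22. A fit of only the groups compared, which by construction has fewer samples, lost 55 of 57 named genes. Run 1 alone (84 cells) lost 54 of 57. Of the named genes tested in run 2 alone (86 cells), 13 were lost and 43 kept.

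The primitive endoderm list passed at E4.0 against each earlier stage without each experiment in turn, but not with an estimated correlation (adjusted p = 0.101 and 0.105). Counts of genes moved. Against E3.25 (195 genes), 129 passed with log2(mean TPM + 1), 361 with no filter, 0 with only the groups compared, 23 in run 1 and 420 in run 2. Against E3.75 (165 genes), 70 passed with log2(mean TPM + 1), 105 after quantile normalization, 0 with only the groups compared, 18 in run 1 and 250 in run 2. For E3.75 against E3.25 (0 genes), 1 passed with log2(mean TPM + 1), 90 with no filter and 1 in run 1.

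For LY at 16 hours (0 genes), 1 gene passed with log2(TPM + 10), 1 with log2(mean TPM + 1), 1 with no filter, 1 with weights by number of cells and 1 without cells of low detection. For LY at 24 hours (0 genes), 1 passed in run 1. For 24h against 16h DMSO (1 gene), 2 passed with log2(TPM + 0.1), 3 with no filter, 6 with the filter at 50% of cells, 11 with weights by number of cells, and 0 each after quantile normalization, with only the groups compared, in run 1, in run 2 and with genes detected as a covariate. For 16h DMSO against E3.25 (6 genes), 13 passed with log2(TPM + 10), 81 with no filter, 10 with the filter at 50% of cells, 10 after quantile normalization, 49 with only the groups compared, 30 with weights, 2 without cells of low detection, 1 in run 1, 1 with genes detected as a covariate, 1 after rescaling TPM and 3 without cells with Cdx2. For 24h DMSO against E3.75 (0 genes), 1 passed with log2(mean TPM + 1), 17 with no filter and 1 in run 2.

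With an estimated correlation 0 of the 31 lists passed in each of the 9 comparisons (lists taken from genes changed at E4.0 are not among them), and 0 for LY averaged over both times. With log2(mean TPM + 1), 9 lists passed for LY at 16 hours, 1 for LY at 24 hours, 1 for E3.75 against E3.25 and 2 for 24h against 16h DMSO. Without cells with Cdx2, 2 passed for 24h against 16h DMSO. Ribosomal proteins at E4.0 against E3.75 turned to higher after quantile normalization (adjusted p = 0.654).

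With the date as a replicate block, which pairs the LY and DMSO arms, 8 lists passed for LY at 24 hours in place of 4. Besides the calls added in the report at 16 and 24 hours and heat shock, higher at 24 hours relative to 16 hours (adjusted p = 0.0427), and epiblast and primitive endoderm markers, lower for LY averaged over both times (adjusted p = 0.0432 each), the block changed no other call. The block was run with the preset correlation only. Without the block, epiblast and primitive endoderm markers for LY averaged over both times each had an adjusted p = 0.897 with an estimated correlation. For the difference between the culture times the smallest such adjusted p of any list was 0.891.

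Leaving out 1 experiment at a time gave 0 to 9 genes for E3.75 against E3.25, 70 to 304 for E4.0 against E3.25, 51 to 278 for E4.0 against E3.75, 0 to 52 for 16h DMSO against E3.25, 0 to 5 for 24h DMSO against E3.75, 0 to 5 for 24h against 16h DMSO and 0 to 1 for LY at 24 hours. An arm left with 1 experiment was assumed to vary like the other groups. Lists ran from 2 to 7 for E3.75 against E3.25, 7 to 12 for E4.0 against E3.25, 6 to 13 for E4.0 against E3.75, 7 to 14 for 16h DMSO against E3.25, 6 to 12 for 24h DMSO against E3.75, 1 to 6 for 24h against 16h DMSO, 3 to 5 for LY at 16 hours and 2 to 5 for the difference between the LY effects. The adjusted p of ribosomal proteins ran from 1.08e-11 to 0.541 for E4.0 against E3.25 and from 3.10e-17 to 0.946 for 16h DMSO against E3.25. That of oxidative phosphorylation ran from 2.55e-05 to 0.895 for E4.0 against E3.25, and that of mitochondrially encoded genes from 3.55e-11 to 0.603 for 24h DMSO against E3.75, each with a change of direction.

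Shares of cells, given as LY minus DMSO in percentage points, moved with the TPM threshold. At 16 hours Nanog and Gata6 together came to -5.19 at a TPM of 50, Nanog only to 7.94 at a TPM of 1 and -31.5 at 50, Gata6 only to 5.56 at 1 and 0 at 50, neither to 36.7 at 50, and Sox2 and Sox17 together to 3.54 at 1. At 24 hours Nanog only came to 16.8 at a TPM of 1, neither Nanog nor Gata6 to 0 at 1 and -1.05 at 50, Sox2 and Sox17 together to -12.4 at 1 and 0 at 50, Sox17 only to 2.78 at 50, and neither of them to 22.5 at 1. Without 1 date, the percent of cells with Nanog and Gata6, LY minus DMSO at 16h, ran from -28.8 to -6.52, and the percent of cells with Nanog only, LY minus DMSO at 24h, from -14.8 to 9.39. Spearman's rho of Nanog with Gata6 was 0.93 at E3.25 in run 1, 0.62 in 16h LY in run 2 and -0.55 in 24h DMSO in run 1. The depth of each cell is unknown, so what it limits cannot be given.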

Other observations

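The tests of the spike-in share, of each lipid list apart and of LY averaged over both times were chosen only after the results had been seen, as was the reading of the test on the 10 highest genes.

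Averaged over both culture times, the genes with the smallest p in the fit with the date block were lower with LY. They were Nupr1, a stress-induced chromatin gene (-2.71 ± 0.82 SE), the desaturase Scd1 (-2.29 ± 0.60), the fatty acid binding gene Fabp3 (-2.46 ± 0.63), Haus8 of the spindle (-2.35), the glutathione transferase gene Gsta4 (-2.39) and Ergic1 of vesicle transport (-1.90). Each was lower on 6 of 6 dates, but choosing by that p favours genes that agree across dates. The errors given are from the fit without the block. In that fit no gene passed limma's threshold (0 genes; 1032 at an unadjusted p under 0.05, 969 of them lower). Fewer genes were detected at a TPM of 1 or more with LY on 6 of 6 dates. With genes detected as a covariate, which itself differed between the arms, 48.3% and 60.4% of genes at an unadjusted p under 0.05 were higher at 16 and 24 hours. With the date block also 0 passed, at a smallest adjusted p of 0.0716. Of 11680 genes, 1017 were lower on 6 of 6 dates and 80 higher, where independent coin tosses give 182.5 each. Cholesterol and fatty acid synthesis fell relative to all genes (medians -0.64 and -0.65, all genes -0.27; adjusted p = 0.0127 each), and the p53 list (0.16; adjusted p = 0.000267) and PI3K AKT components (-0.11; adjusted p = 0.0496) rose. Each had an adjusted p = 0.880 with an estimated correlation.

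At a TPM of 1 or more, Fgf4 was detected in 19 of 31 cells with DMSO and 7 of 31 with LY at 16 hours, and in 15 of 28 and 6 of 24 at 24 hours. Pdgfra was detected in 13 of 31 and 4 of 31, then 20 of 28 and 6 of 24. Gata4 was detected in 3 of 31 and 3 of 31 cells, then 10 of 28 and 3 of 24, Sox17 in 2 of 31 and 4 of 31, then 9 of 28 and 2 of 24, and Sox2 in 19 of 31 and 22 of 31, then 17 of 28 and 12 of 24. Pou5f1 was detected in every cell of the 4 culture groups. These shares were not tested, and LY cells had fewer genes detected.

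Fewer genes were detected per cell with LY at a TPM of 1 or more on 6 of 6 dates, though not on 24h date 2 at a TPM of 10 (3910 with LY, 3848 with DMSO). An uneven split over the sequencing runs is argued against, since the mean difference was -1099 ± 204 (SE) in the run where it was nearer to 0. A few genes taking most of the TPM stays open: the share of the 10 highest genes was 1.15 ± 1.36 percentage points higher with LY, within its error of the bound set before. Less RNA per cell may play a part, but the spike-in share was higher with LY on 4 of 6 dates, which decides nothing at such low shares. An effect of LY on the cells stays open and was not tested.

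Lipid synthesis genes such as Insig1, Hmgcs1, Scd1 and Fasn were lower with LY at 16 hours. Lower detection of genes at their expression level stays open: 0.2% of matched random lists had a median as low as the cholesterol list, but 7 of 31 lists lay outside the middle 95% of their random lists, where 1.55 would by chance for independent genes. For fatty acid synthesis 12.2% did, so lower detection may account for that list. The DMSO experiment with 3 cells is argued against as the whole cause, since 2 of 2 lists passed without that date (adjusted p = 0.0131 each). Both lists passed only with the preset correlation, and no biological explanation was tested.

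Rises outnumbered falls at E4.0 against E3.25, with 72.8% rises among genes at an unadjusted p under 0.05. More genes detected in the E4.0 libraries may account for that balance, since rises were 41.96% with genes detected as a covariate. That covariate is itself tied to stage, so a real broad rise stays open. A difference between the days of collection stays open for this balance, since 2 days per stage are too few to test it, and 52.4% of the genes higher at E4.0 were higher in 24h than in 16h DMSO (adjusted p = 0.263 with an estimated correlation). For single genes the spread between days is the error of the test, which 195 genes passed, with Srgn and Foxa2 past it without each experiment in turn, while Gata4 and Lama1 were lost in 3 of 4 such fits, and none of these 4 passed in the fit of only the groups compared.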
